A study of Mus musculus with 6 samples.

How the data were processed

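Testes of 8-week-old mice of 3 inbred strains were compared, C57BL/6, AKR/N and MRL/MpJ, with 2 mice and 2 arrays each, grouped by the strain given in the sample labels. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled after one-cycle cDNA synthesis for a GeneChip. The authors deposited linear intensity values for each probe set. From the values, each array was scaled to the same mean after trimming 2% at each end, 125.001 on each array, with different quantiles between arrays and no log. The summary software, its version and any detection calls are not given in the sources used here, so a probe set without real signal could be recognised only by its low intensity. The series design counts 2 mice per strain, so the spread between arrays includes that between mice.

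The authors' scaling was kept, because the trimmed means differed by less than 2%. Intensities were transformed as log2(intensity + 16), which understates the change of dim genes. Of 45101 probe sets, 64 control probe sets were left out, and 29692 were tested because at least 2 of the 6 arrays lay above the 40th percentile of their array. The platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, and names were taken only from probe sets with 1 symbol. Those tested covered 14477 genes, each represented by its tested probe set of the highest mean. RefSeq gene order of the mouse assembly GRCm38.p6 was used only for which genes neighbour each other.

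Strain means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on mean level; 3 residual and 7.58 prior degrees of freedom). Differences were called at a Benjamini-Hochberg adjusted p under 0.05 in 3 pairwise comparisons and an F test. Gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated and with fry, over the 20 lists with at least 5 tested genes. No list was called with an estimated correlation, where the smallest adjusted p were 0.711, 0.383 and 0.386. Fry, which tests whether a list's genes move one way on balance and compares them with no other genes, called 0, 7 and 1. Its 7 in AKR/N against C57BL/6 were the 6 lists called by camera and that of meiotic recombination and DNA repair. The latter was also its 1 call between MRL/MpJ and AKR/N (adjusted p = 0.011 by fry).

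The 22 lists, of 540 genes with 430 tested, were chosen before the data were examined, as were the tests of the comparisons, the rule for named genes and the alternatives but 1. They hold spermatogonia, spermatocytes, round spermatids, elongating spermatids, Sertoli cells, Leydig cells and steroidogenesis, peritubular muscle, macrophages, endothelium, epididymis, blood, adipose tissue, heat shock proteins, apoptosis, meiotic recombination and DNA repair, antioxidant and glutathione genes, cholesterol synthesis and transport, the MHC and antigen presentation, interferon response, Y-linked genes, the cilium and sperm flagellum, and the proteasome. Some genes stand in more than 1 list, such as Spo11, Dmc1 and Meig1. Named genes are, per comparison, the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between the strains and whose other tested probe sets went the same way. Added to these are up to 4 called members of each list with the smallest adjusted p, or the 2 brightest where none was called. H2-Eb1 and 7 genes were looked up by name after the values were seen or for what is known of the strains. Of the 7, Nnt, Exo1, Galntl6, Fas, Klf1 and Cd3d had a tested probe set and Hc had none; the rule also names Galntl6, Fas, Cd3d and, between MRL/MpJ and AKR/N, Exo1.

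The calculations were tested on simulated data with 200 changed probe sets among 29692 under 2 noise models. The first used the fitted posterior variances; it recovered 72% of 2-fold and 37% of 1.5-fold changes in MRL/MpJ against C57BL/6, with 14 unchanged probe sets called. The second, adopted after that result was seen, drew variances from the fitted prior; it recovered 48% and 26%, with 3 unchanged probe sets called. For MRL/MpJ against AKR/N the models recovered 70% and 48% of 2-fold and 36% and 22% of 1.5-fold changes. They called 9 and 5 unchanged probe sets there. Under the first model, unchanged probe sets made up more of the calls than the adjusted p threshold aims for, in both comparisons. Under the second they did so for MRL/MpJ against AKR/N but not for MRL/MpJ against C57BL/6. The data gave 2052 and 2975 calls in these comparisons, so recovery with 200 changed probe sets may not carry over. A list shifted by 0.3 was called and 0 of the others were. The simulated noise was independent between genes, so this does not test list calls where genes vary together.

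The alternatives were quantile normalization, median centring, no filter and a stricter one, no variance trend, other pseudocounts, a fold minimum, only the arrays compared, the replicate number as a block, the mean of a gene's probe sets, and each array left out in turn. Using each C57BL/6 array in one comparison only, for the correlation and covariance of fold changes, was chosen after seeing the data. The ratio of 3' to 5' control probe sets, a sign of RNA quality, was 1.52 to 1.78 for beta-actin and 0.677 to 0.827 for Gapdh. By strain, the Gapdh ratio was 0.827 and 0.790 in C57BL/6, 0.734 and 0.816 in AKR/N, and 0.677 and 0.758 in MRL/MpJ. Both MRL/MpJ arrays thus lay under both C57BL/6 arrays. Scan dates and batches are not given in the sources used here, so a batch could not be tested.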

Results

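Total RNA from whole testes of 8-week-old mice of 3 inbred strains, C57BL/6, AKR/N and MRL/MpJ, was measured on 6 oligonucleotide arrays, 2 mice per strain, with no treatment. The series compares testis gene expression between the strains. Values are probe set intensities on a linear scale with the same trimmed mean of 125.001 on each array, and the median probe set lay between 28.0 and 30.7 units. Across probe sets, the 2 arrays of a strain correlated at 0.979 in C57BL/6, 0.985 in AKR/N and 0.984 in MRL/MpJ, and arrays of different strains at 0.967 to 0.979; probe sets are not independent replicates. Intensities below are means ± SD with n = 2 mice, fold changes are differences of log2(intensity + 16) with their standard errors (SE), and p-values are limma's, adjusted over the 29692 probe sets tested. The number of arrays limits the precision, and the spread was estimated from all 3 strains together.

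Testes of MRL/MpJ had higher signal than those of C57BL/6 for 6 of 16 genes of Leydig cells and steroidogenesis, and lower signal for 8 of 24 round spermatid markers and 5 of 13 MHC genes. These lists were called by camera, and each had adjusted p = 0.711 with an estimated correlation. Hsd17b3, the enzyme that makes testosterone from androstenedione, stood at 469.8 ± 6.06 against 179 ± 1.9 units (log2 fold change 1.31, SE 0.0846, adjusted p = 5.97e-06). Cyp17a1, another enzyme of androgen synthesis, stood at 3334 ± 136 against 1872 ± 101 units (0.83, adjusted p = 3.51e-05), and Hsd3b1 was higher by 0.79 (adjusted p = 0.000872). Of 16 measured genes in the list of Leydig cells and steroidogenesis, 6 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.27. That list was called by camera at adjusted p = 0.000226, and had adjusted p = 0.711 with an estimated correlation.

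Among 24 round spermatid markers, 8 fell in MRL/MpJ and none rose (14 and 0 adjusted over the list alone). Sun5, which joins the sperm head to the tail, was at 499 ± 26.1 against 868 ± 39.4 units (-0.78, SE 0.0761, adjusted p = 0.000104), and Spaca3, an acrosomal protein, differed by -0.38 (adjusted p = 0.0111, and 0.0886 without MRL/MpJ replicate 1 and 0.0711 without C57BL/6 replicate 1). Among 25 markers of elongating spermatids 4 fell and none rose (5 and 0 adjusted over the list alone). They included Akap3, a protein of the fibrous sheath of the sperm tail, at 4149 ± 278 against 6604 ± 490 units (-0.67, adjusted p = 0.000186), and Tekt2 (-0.38, adjusted p = 0.00589, and 0.0524 without MRL/MpJ replicate 1). The medians were -0.22 for round spermatids, and -0.14 without C57BL/6 replicate 1, and -0.14 for elongating spermatids, against -0.07 after quantile normalization and -0.09 after median centring. Camera called both lists at adjusted p = 2.6e-05. Each had adjusted p = 0.711 with an estimated correlation.

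Of 13 measured genes of the MHC and antigen presentation, 5 fell and none rose (7 and 0 adjusted over the list alone). H2-K1 was at 71.7 ± 8.26 against 502 ± 5.92 units (-2.57, SE 0.133, adjusted p = 1.18e-06) and H2-D1 at 49.95 ± 0.786 against 273 ± 11.9 units (-2.13, adjusted p = 4.54e-06). H2-Ab1 (-2.26, adjusted p = 0.0028, and 0.0524 without the variance trend) and H2-Aa (-1.46, adjusted p = 0.00445) also fell. By contrast, H2-Eb1 differed by -0.06 (adjusted p = 0.854) and the 8 members that are not classical genes had a median of -0.07. The list was called at adjusted p = 0.00174; it had adjusted p = 0.711 with an estimated correlation and adjusted p = 0.0613 without the filter on dim probe sets. Of 4 other probe sets for H2-D1, 3 went the same way, and as means of their probe sets H2-K1, H2-D1 and H2-Aa differed by -1.53, -0.95 and -0.92. H2-Ab1 and H2-Aa were dim in MRL/MpJ, and with a pseudocount of 64 they differed by -1.23 and -0.75.

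**Figure D1:**
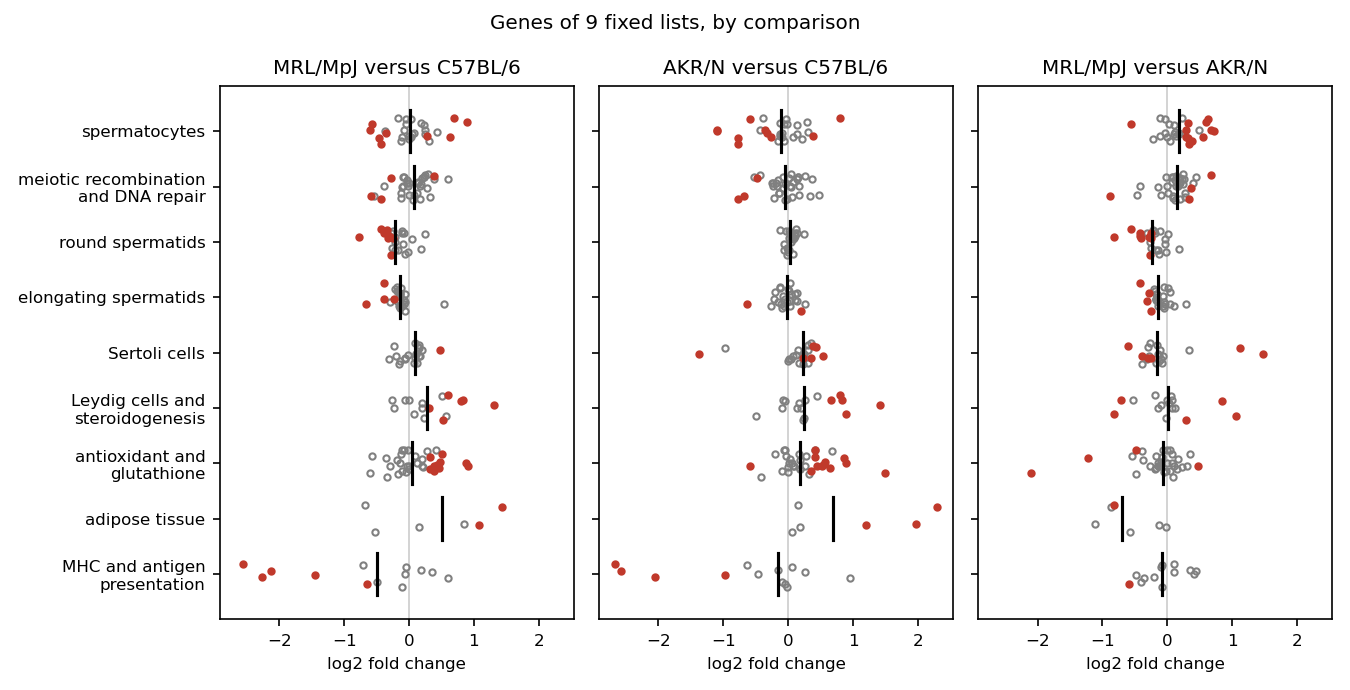
Log2 fold change (horizontal axis, log2 units) of each tested gene of 9 fixed lists (rows) in the 3 comparisons (panels). Filled red points have an adjusted p under 0.05, open grey points do not, and black bars are list medians, such as -0.22 for round spermatids and 0.27 for Leydig cells in MRL/MpJ against C57BL/6.

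With the pseudocount of 16, the largest rises in MRL/MpJ against C57BL/6 were those of Apoc2, an activator of lipoprotein lipase (238 ± 12.2 against 4.28 ± 5.06 units; 3.67), and Vnn1, a pantetheinase (438 ± 50.9 against 27.8 ± 1.92 units; 3.37). Cyp2f2, Serpina3a, Lpo, Cyp2c55, Klb and 1700097N02Rik rose by 2.47 to 3.2. Several of these genes were near the floor in C57BL/6, where the fold depends on the pseudocount: that of Apoc2 was 5.95 with 1 and 2.15 with 64. The largest falls were those of 2010109A12Rik (7.88 ± 1 against 722 ± 91 units; -4.94), 1700104B16Rik (-4.6), 1700063D05Rik (-4.17), Znf41-ps (-3.85), Rd3 (-3.85), Gm19723, the kinase Stk25 (-3.44) and 1700084F23Rik. Rd3 stood at 3.93 units in MRL/MpJ, and its fold was -5.79 with a pseudocount of 1 and -2.30 with 64. Fcgr3, an Fc receptor in the macrophage list, was 667 ± 24.2 against 148 ± 4.63 units (2.05, adjusted p = 4.26e-07), while the 17 macrophage markers had a median of -0.116 with 1 called higher and 1 lower. Single genes that differed in lists without a call included the chaperone Dnajb4 (-1.22, and -0.70 as the mean of its probe sets), the testis proteasome subunit Psma8 (0.77), the glutathione transferases Gstm2 (0.92) and Gsta4 (0.88), and the cholesterol exporter Abca1 (0.78), with adjusted p between 1.8e-06 and 0.000156.

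The other 16 lists had no call in this comparison. Camera gave adjusted p = 0.139 for cholesterol genes (3 higher and 1 lower of 20), 0.143 for antioxidant and glutathione genes (10 and 0 of 34), 0.5 for adipose markers (2 and 0 of 6), 0.505 for apoptosis (4 and 2 of 33) and 0.505 for the proteasome (2 and 0 of 27). It gave 0.527 for peritubular muscle (0 of 12), Y-linked genes (0 and 1 of 5) and the cilium and flagellum (2 and 2 of 28), 0.608 for interferon response (1 and 0 of 20), 0.695 for Sertoli cells (1 and 0 of 21) and 0.716 for endothelium (0 of 13). Meiotic recombination and DNA repair had 0.763 (1 and 3 of 34), spermatogonia 0.785 (1 and 0 of 20), macrophages 0.785, spermatocytes 0.977 (4 and 5 of 28) and heat shock proteins 0.977 (5 and 2 of 34). The epididymis and blood lists had 4 and 2 tested genes and were not tested as lists; Rnase10 fell by 1.58 and Hbb-b2 rose by 1.52, or by -0.82 and 0.65 with a pseudocount of 64.

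In all, 2975 probe sets differed between MRL/MpJ and C57BL/6, 1504 higher and 1471 lower in MRL/MpJ, on 1757 genes, and 287 of the higher and 412 of the lower ones differed at least 2-fold. With each array centred on its median the lower share was 39.4%, against 49.4% as reported. The count was 1801 without C57BL/6 replicate 2, 1483 without MRL/MpJ replicate 1 and 1561 without MRL/MpJ replicate 2.

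**Figure D2:**
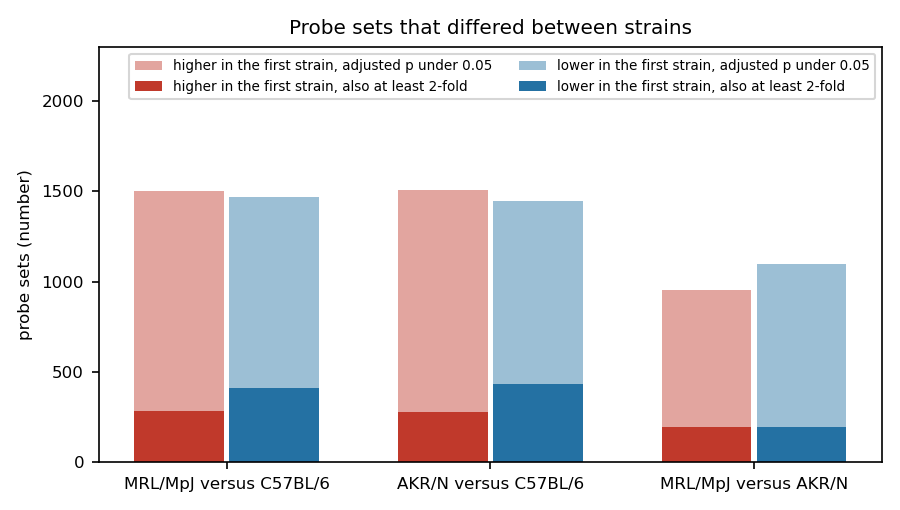
Number of probe sets (vertical axis) with an adjusted p under 0.05 in each comparison (pale bars) and those that also differed at least 2-fold (dark part), higher (red) or lower (blue) in the first-named strain. Among differences of at least 2-fold, 412 fell and 287 rose in MRL/MpJ against C57BL/6, 433 and 281 in AKR/N, and 198 and 196 in MRL/MpJ against AKR/N.

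Testes of AKR/N had higher signal than C57BL/6 for 5 of 16 genes of Leydig cells and steroidogenesis and 11 of 34 antioxidant and glutathione genes, and lower signal for 8 of 28 spermatocyte markers. These lists were called by camera, and each had adjusted p = 0.383 with an estimated correlation. Hsd17b3 reached 506 ± 19.4 against 179 ± 1.9 units (1.42, SE 0.0846, adjusted p = 2.84e-06) and Cyp17a1 3353 ± 213 against 1872 ± 101 units (0.84, adjusted p = 3.31e-05). Star, which carries cholesterol into mitochondria, rose by 0.79 (adjusted p = 0.00767, and 0.0837 without AKR/N replicate 2 and 0.0576 without C57BL/6 replicate 2), and Cyp11a1 by 0.65 on a probe set whose 1 other probe set went the opposite way (0.23 and adjusted p = 0.219 as their mean). Of 16 Leydig and steroidogenesis genes 5 rose and none fell (8 and 0 adjusted over the list alone). The list had adjusted p = 0.000422 by camera and adjusted p = 0.383 with an estimated correlation. Its calls in MRL/MpJ and in AKR/N share the 2 C57BL/6 arrays and are not independent. Between MRL/MpJ and AKR/N its median was 0.0102 (adjusted p = 0.898 by camera).

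In the antioxidant and glutathione list 11 of 34 genes rose in AKR/N and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 0.000322, and adjusted p = 0.383 with an estimated correlation). Gpx3, a secreted glutathione peroxidase, was at 391.9 ± 46.5 against 130 ± 31.8 units (1.495, SE 0.207, adjusted p = 0.00119), and Gsta4 and Gstm1 rose by 0.89 and 0.64. In the Sertoli cell list 5 of 21 genes rose and 1 fell (8 and 2 adjusted over the list alone). Aard rose by 0.54 (adjusted p = 0.000908, and 0.062 without the variance trend). By contrast, Kitl, the Kit ligand made by Sertoli cells, stood at 68.3 ± 6.9 against 203 ± 32.9 units (-1.37, adjusted p = 8.71e-05), or -0.64 as the mean of its probe sets. The Sertoli list was called at adjusted p = 0.00774, with adjusted p = 0.383 with an estimated correlation and adjusted p = 0.054 without C57BL/6 replicate 1 and 0.0529 without AKR/N replicate 1.

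Spermatocyte markers were lower in AKR/N for 8 of 28 genes and higher for 2 (10 and 2 adjusted over the list alone). Smc1b, a meiotic cohesin subunit, was at 588 ± 141 against 1255 ± 18.7 units (-1.09, adjusted p = 0.000458), and Spo11, which makes the breaks that start meiotic recombination, differed by -0.77 (adjusted p = 0.000112). Meiob, a meiotic single-strand DNA binding protein, rose by 0.81 (adjusted p = 0.000673). The list was called at adjusted p = 0.00525 and had adjusted p = 0.383 with an estimated correlation. The MHC list had 4 lower and none higher of 13 (6 and 1 adjusted over the list alone), with H2-K1 at 66.0 ± 12 units (-2.67, adjusted p = 7.87e-07) and H2-D1 at 32.4 ± 0.546 units (-2.58, adjusted p = 9.15e-07); the 8 members that are not classical genes had a median of -0.04. As means of their probe sets H2-K1 and H2-D1 differed by -1.70 and -1.08, with 1 of the 4 other probe sets of H2-D1 the opposite way. The MHC list was called at adjusted p = 0.00568 and had adjusted p = 0.484 with an estimated correlation. Its median of -0.16 depended on the setting. It was -0.08 without the filter on dim probe sets and -0.47 with the 60th percentile filter. Without C57BL/6 replicate 2 it was -0.0157, and without C57BL/6 replicate 1 -0.39.

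Adipose markers, of a tissue that dissection can carry along, rose in 3 of 6 genes (3 adjusted over the list alone). The call was at adjusted p = 0.00607, with adjusted p = 0.484 with an estimated correlation and adjusted p = 0.0911 without the filter on dim probe sets. Scd1, a fatty acid desaturase, was 199.5 ± 10.4 against 77.4 ± 0.911 units. Fabp4 and Car3 varied widely within AKR/N, at 111 ± 86.6 and 128 ± 89.7 units, with Fabp4 at 172 units on AKR/N replicate 1 and 49.5 on AKR/N replicate 2. Its adjusted p was 0.00498, and 0.0568 without C57BL/6 replicate 2.

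With the pseudocount of 16, the largest rises in AKR/N were those of Apoc2 (418 ± 9.82 units; 4.44), Vnn1 (3.31), 9430014N10Rik (3.29), Cd3d, a part of the T cell receptor complex (143 ± 42.5 against 1.43 ± 0.375 units; 3.16), Lpo, Cyp2c55, Klb and Arg2. With pseudocounts of 1 and 64 the folds were 6.75 and 2.82 for Apoc2 and 5.86 and 1.65 for Cd3d. The largest falls were those of Galntl6 (2.25 ± 0.973 against 516 ± 18.6 units; -4.87), 1700104B16Rik (-4.73), 2010109A12Rik (-4.37), 1700063D05Rik, Hoxb5os, 1700084F23Rik, Dapp1 and Znf41-ps. The fold of Galntl6 was -7.35 with a pseudocount of 1, -3.13 with 64 and -2.76 as the mean of its probe sets. Akap3 was lower in AKR/N too (-0.64, adjusted p = 0.000253, and -0.41 as the mean of its probe sets), while among the round spermatid markers 0 of 24 were called (adjusted p = 0.515 for the list) and among elongating spermatid markers 1 rose and 1 fell (0.498).

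The remaining lists had no call by camera in AKR/N against C57BL/6, while fry called meiotic recombination and DNA repair (adjusted p = 0.024). Camera gave adjusted p = 0.0966 for cholesterol genes, 0.115 for meiotic recombination and DNA repair, 0.314 for macrophages, endothelium and Y-linked genes, 0.344 for the cilium and flagellum, 0.581 for spermatogonia, 0.587 for apoptosis, 0.845 for the proteasome, 0.943 for heat shock proteins and interferon response, and 0.95 for peritubular muscle. In the untested epididymis and blood lists, Rnase10 fell by 1.87, or -0.92 with a pseudocount of 64. Hbb-b2 rose by 0.88 (adjusted p = 0.0476, up to 0.27 with any array left out, and 0.0768 with a pseudocount of 64).

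AKR/N and C57BL/6 differed in 2960 probe sets, 1510 higher and 1450 lower in AKR/N, on 1705 genes, of which 281 and 433 were at least 2-fold. Centring each array on its median gave a lower share of 39.7%, against 49% as reported. The count was 1549 without C57BL/6 replicate 2, 1479 without AKR/N replicate 1 and 1290 without AKR/N replicate 2.

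**Figure D3:**
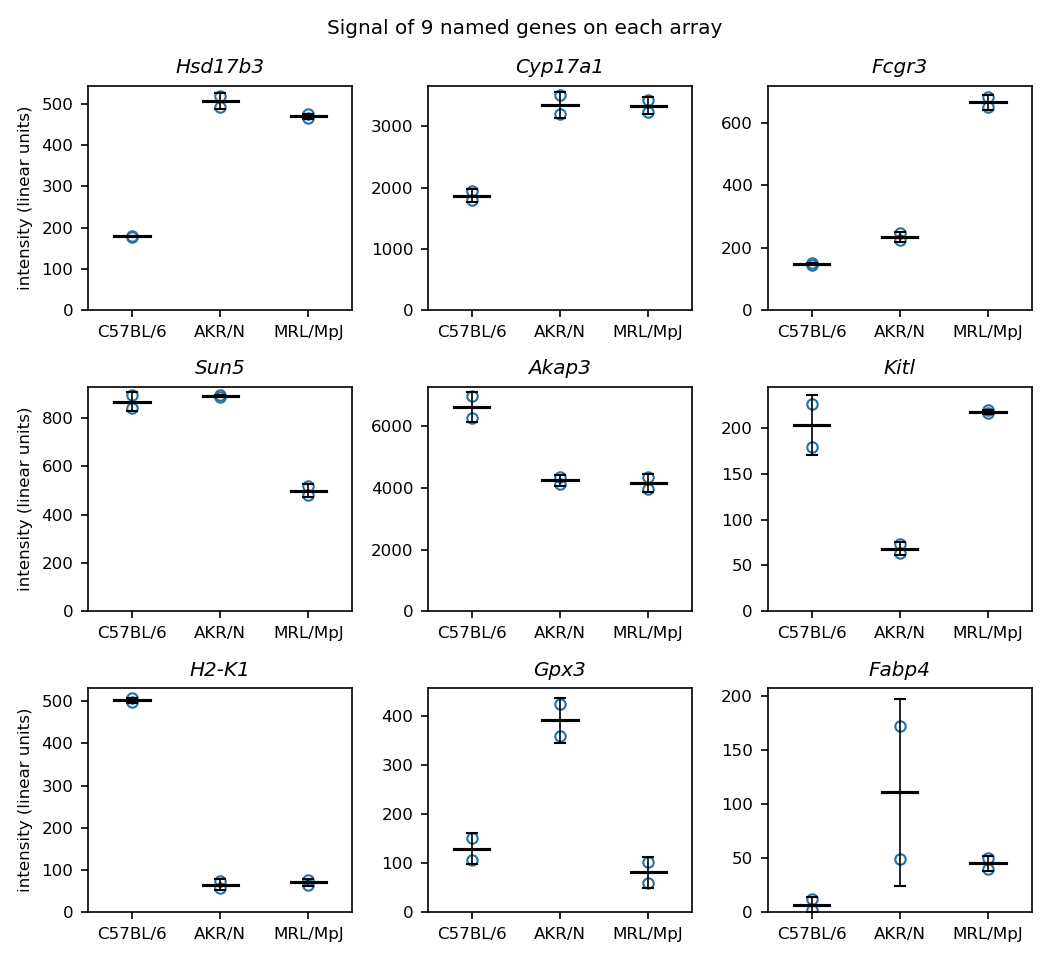
Intensity (vertical axis, linear units) of 9 named genes on each array (circles) by strain (horizontal axis), with the mean of 2 mice (thick bar) and its SD (thin bar). Sun5 was lowest in MRL/MpJ (499 units), Kitl in AKR/N (68.3 units), and H2-K1 was highest in C57BL/6 (502 units), whereas Fabp4 spread from 49.5 to 172 units within AKR/N.

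Between MRL/MpJ and AKR/N, 9 of 24 round spermatid markers were lower and 11 of 28 spermatocyte markers higher in MRL/MpJ. Both lists were called by camera, and had adjusted p = 0.406 and adjusted p = 0.386 with an estimated correlation. Of 24 round spermatid markers 9 fell and none rose (16 and 0 adjusted over the list alone), with a median of -0.231; Sun5 was at 499 ± 26.1 against 892 ± 3.79 units (-0.82, SE 0.0761, adjusted p = 0.000109). The list was called at adjusted p = 1.59e-07 and had adjusted p = 0.406 with an estimated correlation. Of 25 elongating spermatid markers 4 fell and none rose (6 and 0 adjusted over the list alone), Tekt2 among them (-0.42, adjusted p = 0.0054, and 0.0648 without AKR/N replicate 2). That list was called at adjusted p = 0.000701, with adjusted p = 0.563 with an estimated correlation and adjusted p = 0.0527 without MRL/MpJ replicate 1.

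Spermatocyte markers rose in MRL/MpJ against AKR/N in 11 of 28 genes and fell in 1 (13 and 1 adjusted over the list alone), with adjusted p = 0.000392 and adjusted p = 0.386 with an estimated correlation. Sycp1 and Sycp2, parts of the synaptonemal complex that pairs meiotic chromosomes, stood at 949 ± 36.7 against 578 ± 160 units and at 1560 ± 59.7 against 1017 ± 216 units (0.73 and 0.62; adjusted p = 0.0121 and 0.00916, and 0.0796 and 0.0681 without MRL/MpJ replicate 1; Sycp1 had 0.0584 without MRL/MpJ replicate 2). Without AKR/N replicate 2 their fold changes were 0.45 and 0.41, and the median of the spermatocyte list was 0.101 against 0.178 with all arrays. Meiotic recombination and DNA repair genes had 3 higher and 1 lower of 34 (6 and 1 adjusted over the list alone; adjusted p = 0.0103, and adjusted p = 0.386 with an estimated correlation). This list shares genes with the spermatocyte list, with Spo11 and Dmc1 among those higher. Both calls also share the AKR/N arrays with the fall of spermatocyte markers in AKR/N against C57BL/6, and are not independent of it. In MRL/MpJ against C57BL/6 the spermatocyte list was not called (adjusted p = 0.977 by camera). Dmc1, the meiotic recombinase, rose by 0.67 (adjusted p = 0.0123, and 0.0655 to 0.0913 without any single MRL/MpJ or AKR/N array), and the exonuclease Exo1 was at 39.0 ± 1.98 against 85.2 ± 2.42 units (-0.88, adjusted p = 0.0108, and 0.0536 to 0.083 without any single one of these arrays; -0.54 with a pseudocount of 64).

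Sertoli cell genes had 4 lower and 2 higher of 21 in MRL/MpJ against AKR/N (4 and 3 adjusted over the list alone). Kitl was higher on its brightest probe set, at 217 ± 2.54 against 68.3 ± 6.9 units (1.47, adjusted p = 8.23e-05), but 1 of its 2 other probe sets went the opposite way, and the mean of its probe sets differed by 0.49 (adjusted p = 0.0608). The call at adjusted p = 0.0272 had adjusted p = 0.395 with an estimated correlation, adjusted p = 0.172 without AKR/N replicate 1, 0.0527 without MRL/MpJ replicate 1 and 0.0508 after quantile normalization. Adipose markers had 1 lower of 6 (2 adjusted over the list alone; adjusted p = 0.0424, adjusted p = 0.563 with an estimated correlation, 0.096 without the filter, 0.0717 with the 60th percentile filter and 0.0577 with a pseudocount of 1). That adjusted p was 0.323 without AKR/N replicate 1, 0.149 without MRL/MpJ replicate 2, 0.0538 without C57BL/6 replicate 1 and 0.0513 without C57BL/6 replicate 2.

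With the pseudocount of 16, the largest rises in MRL/MpJ against AKR/N were those of Galntl6 (617 ± 158 against 2.25 ± 0.973 units; 5.09), Hoxb5os (3.11), 4933433G15Rik, Dapp1, Mybl1, a transcription factor of meiotic cells (437 ± 34 against 54.9 ± 1.29 units; 2.67), Cyp2f2, Csl and Fyb. The fold of Galntl6 was 3.34 with a pseudocount of 64 and 3.17 as the mean of its probe sets. The largest falls were those of the blood cell kinase Map4k1 (20.9 ± 8.77 against 569 ± 28.5 units; -4.00), Slfn5os (-3.78, and -6.45 and -2.14 with pseudocounts of 1 and 64), 9430014N10Rik, 4930523O13Rik, Rd3, Gm19723, Cd3d and 4921534H16Rik. Within lists without a call, Gpx3 (-2.10) and Gsta3 (-1.23) were lower, Fcgr3 (1.44), Hsd3b1 (0.84) and Abca1 (0.84) were higher, and Cyp11a1 fell by 0.72. Without the variance trend Hsd3b1 and Cyp11a1 were not called (adjusted p = 0.0679 and 0.0746).

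No call was made for the other lists between MRL/MpJ and AKR/N. Camera gave adjusted p = 0.101 for endothelium, 0.118 for antioxidant and glutathione genes, 0.266 for macrophages, 0.551 for peritubular muscle and the proteasome, 0.673 for interferon response, and 0.898 for spermatogonia, Leydig cells, heat shock proteins, apoptosis, cholesterol genes, the MHC, Y-linked genes and the cilium and flagellum. In 6 cases the median, mean and test of a list differed in sign, none of them a call: spermatocytes and macrophages in MRL/MpJ against C57BL/6, cholesterol genes in MRL/MpJ against AKR/N, and heat shock proteins in all 3 comparisons, with a median under 0 and a test upwards.

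MRL/MpJ and AKR/N differed in 2052 probe sets, 955 higher and 1097 lower in MRL/MpJ, on 1260 genes, of which 196 and 198 were at least 2-fold. Centring each array on its median gave a lower share of 51.4%, against 53.5% as reported. The count was 1327 without the filter on dim probe sets, and 900, 694, 890 and 811 without AKR/N replicate 1, AKR/N replicate 2, MRL/MpJ replicate 1 and MRL/MpJ replicate 2.

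Over the 3 strains together limma's F test called 4487 of 29692 probe sets, on 2648 genes. C57BL/6 stood apart from both other strains at 629 probe sets with higher and 734 with lower signal, MRL/MpJ at 283 and 469, and AKR/N at 322 and 400, together 2837. The F test called 2698 without AKR/N replicate 2, and 2897 to 2978 without AKR/N replicate 1 or either MRL/MpJ array; those setting a strain apart numbered 1350 without AKR/N replicate 2, 1855 without C57BL/6 replicate 2, and 1541 to 1555 without AKR/N replicate 1 or either MRL/MpJ array. Lists that were independent would share 71.8 and 76.5 probe sets for C57BL/6, 48.4 and 54.4 for MRL/MpJ, and 55.8 and 46.6 for AKR/N. In 20 simulations of unchanged strains at most 1 was found, since almost nothing is called there. Neither gives the number that shared arrays would add where many probe sets differ. Fold changes against C57BL/6 in MRL/MpJ and in AKR/N correlated at 0.635 across probe sets, against 0.499 simulated for unchanged strains that share the C57BL/6 arrays, and their covariance was 0.105 against 0.0252. The difference of covariances was 0.0793. With each C57BL/6 array used in one comparison only, a setting chosen after seeing the data, the covariance was 0.0733 and 0.0782 in the 2 ways of dividing them, and the correlation 0.375 and 0.41 with 1 control array each. The 2 contrasts that set a strain apart share that strain's arrays, in each of the 3 strains alike. Sharing may add to each count, and more so for a strain whose arrays vary more, since the spread was estimated from all 3 strains. The 2 arrays of C57BL/6 correlated least, at 0.979 against 0.985 in AKR/N and 0.984 in MRL/MpJ. Whether sharing explains why C57BL/6 had the most was not tested. C57BL/6 replicate 2 correlated least with the arrays of the other strains, at 0.967 to 0.968.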

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

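The use of each C57BL/6 array in one comparison only was chosen after seeing the data; the covariance of fold changes against C57BL/6 was then 0.0733 and 0.0782 in place of 0.105, by construction without the shared arrays. Camera with an estimated correlation called 0, 0 and 0 lists in place of 4 (MRL/MpJ against C57BL/6), 6 (AKR/N against C57BL/6) and 6 (MRL/MpJ against AKR/N), and fry 0, 7 and 1; the cause was not tested. Without the variance trend limma called 1212, 1138 and 421 probe sets in place of 2975, 2960 and 2052, and 1366 by the F test in place of 4487. Probe sets setting 1 strain apart then numbered 930 in place of 2837, with 201 for MRL/MpJ, 178 for AKR/N and 551 for C57BL/6 in place of 752, 722 and 1363; the cause was not tested. A 2-fold minimum left 699, 714 and 394 probe sets by its construction, and 620 setting a strain apart (137, 145 and 338). Without the filter on dim probe sets MRL/MpJ against AKR/N had 1327 calls, and MRL/MpJ and AKR/N stood apart at 496 and 471; 45037 probe sets were then tested. Leaving out 1 array, whose strain's other array is then assumed to vary like the other strains, gave 1483 to 2545, 1290 to 2607 and 694 to 2191 calls, 2698 to 3911 by the F test, and 1350 to 2365 setting a strain apart (325 to 601, 274 to 678 and 751 to 1133); fewer arrays are one reason by construction. It gave 4 to 5, 5 to 6 and 4 to 7 lists. Quantile normalization, median centring, the 60th percentile filter, and pseudocounts of 1 and 64 kept each of these counts within 1.5 times, as did fits of only the 4 arrays compared for the pairwise and list counts, the only ones they give. Same-numbered arrays deviated together only weakly, at correlations of 0.0493, 0.0425 and 0.0466, which leaves open whether the numbers pair the samples. With the replicate number as a block the counts rose to 3510, 3492 and 2549, and to 5332 by the F test, with 4, 6 and 6 lists. The called lists lost their call in 31 of 192 values from other settings (16 with the estimated correlation and 9 with fry) and 9 of 96 with 1 array left out, with no reversal. Of 201 calls of named genes, 117 held without each array and 93 in all settings; 1 gene reversed, Dnali1 in MRL/MpJ against C57BL/6, at -0.17 as the mean of its probe sets against 0.26, because its other probe set went the opposite way. Genes near the floor, such as Apoc2 in C57BL/6 at 4.28 ± 5.06 units, have folds that depend on the pseudocount.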

Other observations

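Of the tests below, those of the MHC genes, of macrophage markers beside them and of the spermatid share were chosen only after the result was seen, the bounds that decide the neighbour tests were loosened after their values were known, and the runs of 40 genes had no bound at all. Klf1, an erythroid transcription factor, was looked up by name after its values were seen: it had 149.8 ± 4.59 units in MRL/MpJ and 161 ± 5.89 in AKR/N against 32.95 ± 0.675 in C57BL/6 (1.76 and 1.86, adjusted p = 1.12e-05 and 7.08e-06). Nnt, a mitochondrial transhydrogenase looked up because some C57BL/6 substrains are known to carry a deletion in it, had 587.5 ± 38.4 and 694 ± 69.3 units against 380 ± 15.9 (0.61 and 0.84, adjusted p = 0.0021 and 0.000243), with 1 other probe set in the same direction. The substrain is not given in the sources used here.

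The first pattern is that differences of at least 2-fold against C57BL/6 lean towards lower signal, 58.9% in MRL/MpJ and 60.6% in AKR/N, and those of at least 4-fold too, 68.6% and 63.0% against 55.4% between MRL/MpJ and AKR/N, with classical MHC genes among them. Probes that match the C57BL/6 sequence may bind other alleles less well. As the source of the calls as a whole the values argue only weakly against this. Lower calls made up 49.45% and 48.99% where over 60 was predicted. That balance depends on scaling (39.4% and 39.7% with median centring, 51.7% and 49.4% with quantile normalization). For genes with a 2-fold change, the brightest other probe set was asked to move at least 0.5 times as far the same way. In MRL/MpJ against C57BL/6 it did so in 24.1% of falls and 35.7% of rises (Fisher's exact p = 0.0378). In AKR/N against C57BL/6 it did so in 19% and 32% (Fisher's exact p = 0.0134). Between MRL/MpJ and AKR/N the shares were 26.5% and 18.3% (Fisher's exact p = 0.263). Most of these 2-fold changes, rises included, were thus not followed by the gene's other probe set. The 5 classical MHC genes had medians of -2.13 and -2.06 while the other 8 members had -0.0719 (95% bootstrap interval -0.644 to 0.36) and -0.0371 (-0.159 to 0.26), although H2-Eb1 itself differed little in MRL/MpJ. Fewer macrophages are argued against by medians of -0.116 and 0.0213 over 17 macrophage markers where -0.5 or lower was needed. That bound was set after the fact near the MHC list median in MRL/MpJ (-0.496). In AKR/N that median was -0.159, so the bound is less apt there. Real differences of expression between MHC haplotypes stay open, as no test separates them from probe mismatch.

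Spermatid markers lay lower in MRL/MpJ than in both other strains by list median. Called lower were 8 of 24 round spermatid markers against C57BL/6 and 9 of 24 against AKR/N. Of elongating spermatid markers, 4 of 25 were called lower in each comparison, but they were not the same genes. Tekt2 was called in both. Akap3 was called only against C57BL/6, against which it was lower in AKR/N too (-0.64). A signal-dependent bias of the arrays or of the authors' scaling was set against 10000 random lists of matched signal. For round spermatids these were as low at permutation p = 1e-04 in both comparisons, the smallest they can give. This argues against such a bias as the whole cause there. For elongating spermatids they were as low at permutation p = 0.038 and 0.0086, though matched lists had medians of -0.0374 to -0.0778 themselves. Against C57BL/6 the elongating spermatid median was -0.07 after quantile normalization and -0.09 after median centring, so scaling may be part of it. The draws took genes as independent, and both comparisons share the MRL/MpJ arrays. A smaller share of spermatids and nothing else would raise the markers of other cell types alike. A permutation of 126 genes between 7 such lists, which took genes as independent too, gave p = 0.135 against C57BL/6 and p = 0.0323 against AKR/N. A smaller share thus cannot be told apart from a change in several cell types, the 2 comparisons deciding differently. The spread against AKR/N may also stem from AKR/N rather than MRL/MpJ. In AKR/N against C57BL/6, camera called the spermatocyte, Sertoli and Leydig lists (adjusted p = 0.00525, 0.00774 and 0.000422). Strain itself stays an open explanation. The adjusted p by camera with an estimated correlation leaves the pattern itself a hypothesis. It was 0.711 and 0.406 for round spermatids, and 0.711 and 0.563 for elongating spermatids.

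Called genes had a called next gene along the chromosome in 15.8%, 14.6% and 11.7% of cases in MRL/MpJ against C57BL/6, AKR/N against C57BL/6 and MRL/MpJ against AKR/N, against means of 12.1%, 11.8% and 8.72% for 10000 random placements (permutation p = 1e-04, the smallest possible, 2e-04 and 1e-04). Blocks of shared descent may underlie this, but the bound fixed beforehand asked for a value above each random placement, with and without neighbours of the same first 3 letters, and 14.6 lay under the highest, 14.7, as did 13.7 under 14.8 and 11.4 under 11.6 without such neighbours, so that bound was missed. Descent is not supported by it and is left open only because each share still lay above the mean of its placements, at permutation p of 0.0075 or less, which the highest of 10000 draws was too strict a bound to show. Neighbouring family members that share probes are argued against as the whole source, since without neighbours of the same first 3 letters the shares were 15%, 13.7% and 11.4% (permutation p = 1e-04, 0.0075 and 4e-04), although 13.7 and 11.4 did not reach the bound fixed beforehand for this explanation either. In runs of 40 neighbouring genes, a size chosen by hand, 24 of 350 held no call between MRL/MpJ and AKR/N where random placement gave 9.08; co-regulated neighbours were not tested.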
